A study of Mus musculus with 18 samples.

How the data were processed

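RNA was sequenced from 18 mouse tumours, 3 in each of 6 groups: cryoablation, radiofrequency ablation and cryo-thermal therapy of another tumour of the animal, each alone and with an antibody against PD-1. Per the labels, RNA was extracted with TRIzol and a silica column with DNase, and libraries were made with a VAHTS Universal V6 kit; the strand, the tumour line, the mouse strain and the day of collection were not given in the sources used here. The deposited table holds FPKM values made by the authors, which divide a gene's fragment count by its length and by the mapped fragments of the library. HTSeq 0.11.2 is named in the submitters' processing notes, and the aligner, genome build, annotation release and filters were not given in the sources used here. The table has 26538 genes with NCBI symbols and gene numbers, 18548 protein coding and 7990 non-coding, and 0 genes are at 0 in all 18 tumours. Each tumour has a column of its own, with 0 pairs of identical columns and 0 columns of other samples. FPKM sums ran from 408042 to 442383 and genes at 0 from 5995 to 7191 per tumour. Pearson r across genes on the log2 scale was 0.972 to 0.995 within groups and 0.955 to 0.993 between groups.

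The table holds no fragment counts, so depth was estimated. Of 25465 low values of 2749 genes, 99.62% were whole multiples of one step per library within a tolerance of 0.05 fragments, which gave relative depths of 0.985 to 1.018. With exon lengths of GENCODE release vM21 for 1557 matched genes, the most frequent depth was 38100000 fragments, shared by 264 genes, and the range over tumours was 37500000 to 38800000. The release the authors used is unknown, so this depth is approximate, and no interval or limit was computed from it.

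Values were analysed as log2(FPKM + 1), a scale on which fold changes of genes with low FPKM are smaller than the ratio of their FPKM values. Genes with a mean FPKM of at least 0.5 over all tumours were kept, 12587 in all. A linear model with a mean per group was fitted to all 18 tumours with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean level. Tests were 2-sided, and p-values were adjusted by Benjamini and Hochberg over the genes of each comparison with a threshold of 0.05. The plan had a branch for count data, which was not used because the table holds FPKM. The 13 comparisons were 9 between 2 groups, 2 differences of the anti-PD-1 effect between ablations, the mean effect of anti-PD-1, and cryo-thermal therapy against the mean of the other ablations. They share tumours and are not independent of each other, and no adjustment was made over comparisons. With 3 tumours against 3, an exact permutation test of a single value cannot give a p under 0.1. Spreads are SD over 3 tumours unless SE is written, and SE is limma's error of the log2 fold change. Beside a list median, the median of the genes' own SE is given, which is not an error of that median. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the other steps.

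Before the data were examined, 30 gene lists of cell types, pathways and tissues were fixed, along with the comparisons, the tests and the rule for genes named in the text. Of 455 list entries 435 were found by symbol, 1 by NCBI gene number and 19 were not in the table. Some genes are in more than 1 list, such as Gzmb and Prf1 in those of cytotoxic lymphocytes and NK cells. Ctla4, Ido1 and Cxcl9 are shared between lists as well, so the lists are not separate measures of cell types. Lists with at least 5 measured members were tested with camera of limma, which asks whether a list moves relative to the other genes, with a preset correlation of 0.01 between genes, and again with an estimated correlation. Counts adjusted over the list alone adjust the limma p-values over that list's genes only, without adjustment over lists or comparisons. Genes of a list can move together, with an estimated correlation of 0.898 for MHC class I presentation, so such counts are not independent signals. The 27 lists tested left out B and plasma cells, melanocytes and melanoma, and mitochondrially encoded genes, each with fewer than 5 members past the filter. A further 6 lists were written after the data were seen, for heat shock chaperones, cold-inducible genes, clock output genes, the positive arm of the clock, liver secreted proteins, and hair follicle and melanocyte genes.

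The named genes were the 10 with the largest positive and the 10 with the largest negative change among those past the threshold whose values did not overlap between groups, which 10% of random splits of 3 against 3 would give for a gene. Predicted genes, clones, and immunoglobulin and T cell receptor segments were left out. Where fewer than 5 genes passed, the 5 with the smallest p in each direction were taken and described as not passing. Up to 4 members of each list that passed and 12 genes chosen for the series title, of which 11 are reported, were added, and for the differences of effects the 5 genes with the smallest adjusted p. Reads of near-identical genes, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, Tgtp1 and Tgtp2, and the granzymes Gzmc to Gzmg, may have been divided between the copies, so the value of each copy is uncertain.

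The alternatives tried were a pseudocount of 0.1, no filter on low values, quantile normalization, rescaling each tumour to the same FPKM sum, fits of only the groups compared, array weights, a replicate block, and leaving out each tumour of a comparison in turn. Further ones chosen after the data were seen were the mean level of the keratinocyte list as a covariate, that of the erythroid list as a covariate, leaving out 3 skin-rich tumours, and fry, a rotation test of each list by itself. The procedure was tested on simulated data with 200 changed genes among 12587. For cryo-thermal therapy against cryoablation limma recovered 71.6% of genes changed by a log2 of 0.5 and 95.5% of those changed by 1, with 10 false calls; for cryo-thermal therapy against the mean of the other ablations it recovered 80.6% and 97%, with 14 false calls. Without a simulated change 0 of 27 lists were called by camera and by fry, and a T cell list shifted by 1 was recovered with 0 other lists. The simulated genes were independent, whereas the measured T cell genes had an estimated correlation of 0.754. The simulation therefore did not test how camera with the preset correlation behaves on correlated lists.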

Results

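RNA sequencing measured gene expression in 18 mouse tumours that had not themselves been treated, each taken from an animal in which another tumour had been ablated. The tumours fell into 6 groups of 3. Cryoablation destroys tissue by freezing, radiofrequency ablation destroys it by heating with an alternating current, and cryo-thermal therapy joins freezing and radiofrequency heating. Each ablation was given alone or with an antibody against PD-1, an inhibitory receptor on T cells. The series title concerns a CCL5-positive mature state of myeloid cells, T cell infiltration and the response to anti-PD-1. A group without ablation was not analysed here, so every comparison is between treated animals. The sequencing depth estimated from the values was 37500000 to 38800000 fragments per tumour, and relative depth ran from 0.985 to 1.018. Of the 18, 3 tumours held much hair follicle RNA, with mean log2 levels of 2.88, 3.14 and 2.72: cryoablation plus anti-PD-1 replicates 1 and 2 and cryo-thermal plus anti-PD-1 replicate 1, called skin-rich here. The labels do not say whether the 3 tumours of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

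Among 11 genes chosen in advance for their bearing on the question, cytotoxic T cell genes were highest after cryo-thermal therapy plus anti-PD-1. Ifng (NCBI gene 15978), the interferon made by activated T and NK cells, measured 0.0505 ± 0.0543 FPKM (SD, n = 3) after cryoablation, 1.27 ± 0.869 after cryo-thermal therapy and 3.28 ± 0.574 after cryo-thermal therapy plus anti-PD-1. Cd8a (12525), a co-receptor of cytotoxic T cells, measured 0.225 ± 0.0666, 3.54 ± 1.62 and 5.66 ± 0.83 FPKM in the same groups. Gzmb (14939), a granzyme that kills target cells, reached 23.7 ± 0.618 FPKM after cryo-thermal therapy plus anti-PD-1 against 4.18 ± 1.72 after cryoablation. Ccl5 (20304), a chemokine that draws T cells, measured 6.53 ± 0.907 FPKM after cryo-thermal therapy and 8.23 ± 1.56 with anti-PD-1 added. It measured 3.16 ± 1.47 and 2.73 ± 0.204 FPKM in the matching radiofrequency groups and 2.42 ± 0.255 after cryoablation plus anti-PD-1. After cryoablation alone its mean was 5.58 ± 4.88 FPKM, with 11.2 in replicate 1, 2.57 in replicate 2 and 2.95 in replicate 3. Cxcl10 (15945), an interferon-induced chemokine, had its lowest mean after cryo-thermal therapy, 63.5 ± 21.3 FPKM, and its highest after radiofrequency ablation plus anti-PD-1, 357 ± 10.7 FPKM. The other genes of the 11 were Cd4 (12504), Cd3e (12501), Pdcd1 (18566), Cd274 (60533), Cxcl9 (17329) and Itgam (16409).

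**Figure D1:**
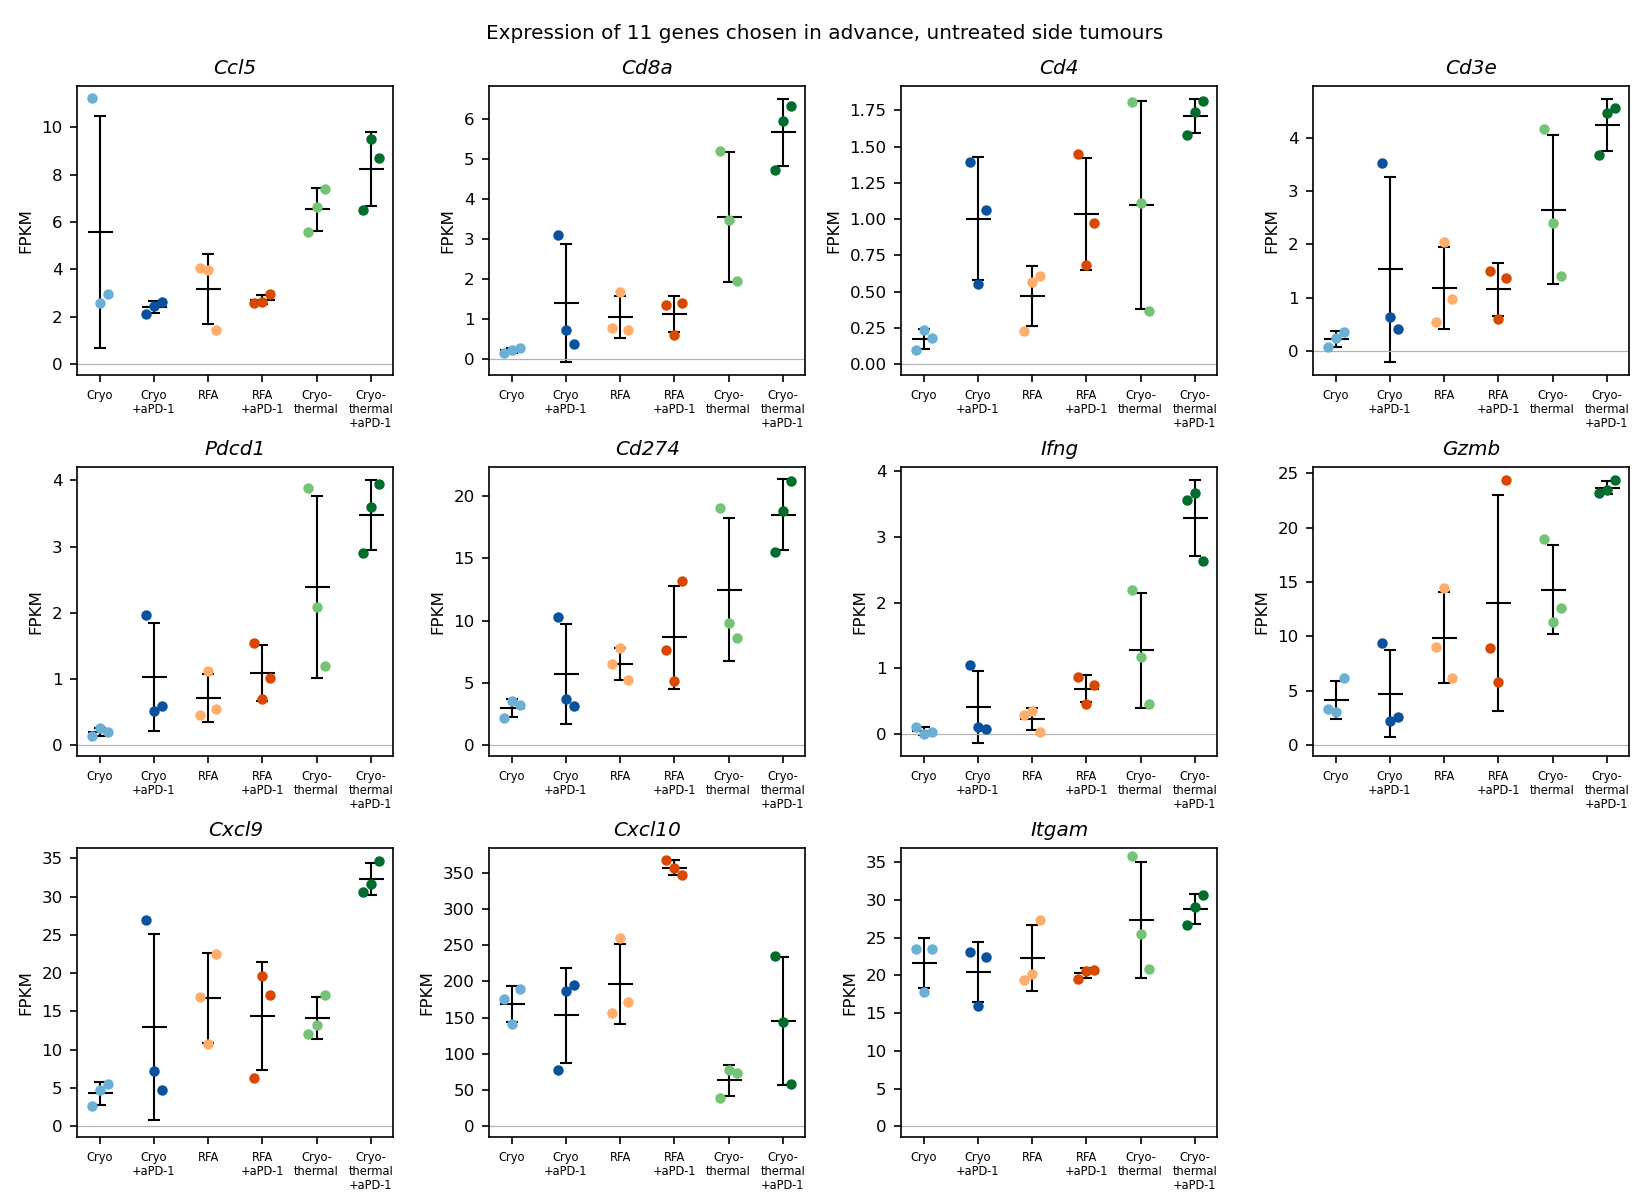
Expression of 11 genes chosen in advance, in FPKM on a linear axis, in each of the 18 tumours by treatment (Cryo, cryoablation; RFA, radiofrequency ablation; aPD-1, antibody against PD-1). Points are tumours, the black dash is the mean of 3 and the bars are 1 SD; Ifng measured 3.28 ± 0.574 FPKM after cryo-thermal therapy plus anti-PD-1 and 0.0505 ± 0.0543 after cryoablation.

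The first comparison asked how the untreated tumour differed after cryo-thermal therapy and after cryoablation, both without anti-PD-1. Interferon-induced genes rose. Gbp4, a guanylate-binding protein, went from 1.85 ± 0.81 to 24.7 ± 10.0 FPKM (n = 3 each; log2 fold change 3.15, SE 0.56, adjusted p = 0.00555). All 17 measured members of the interferon gamma response list rose (17 adjusted over the list alone; median 2.52), as did all 18 of the type I interferon response list (18 adjusted over the list alone; median 2.15). The leading genes also included the interferon-induced GTPases Tgtp1 at 3.56, Iigp1 at 3.52 and Igtp at 3.07. For both lists the camera adjusted p, at most 4.49e-14, became adjusted p = 0.203 with an estimated correlation.

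Antigen presentation and T cell genes were higher as well. All 16 measured genes of MHC class I presentation rose (16 adjusted over the list alone; median 1.17), among them Psmb9, an immunoproteasome subunit, at 2.37. All 8 genes of MHC class II presentation rose (8 adjusted over the list alone; median 2.00), and Cd74, the invariant chain, went from 104 ± 31.3 to 553 ± 167.0 FPKM. Of 12 T cell genes 11 rose (11 adjusted over the list alone), including the CD3 chains Cd3d by 1.36 and Cd3g by 1.96 and the kinase Lck by 1.52. The mean log2 level of the T cell list was 2.05, 1.64 and 1.04 in cryo-thermal replicates 1, 2 and 3 and 0.44 to 0.55 in the cryoablation tumours, and Jchain, a gene of antibody-secreting cells, measured 4.77, 4.06 and 0.637 FPKM in the first 3 and at most 0.0906 in the others. Of 14 cytotoxic lymphocyte genes 11 rose (12 adjusted over the list alone), among them Cd8a by 1.83, Nkg7 by 2.10 and the chemokine Xcl1 by 1.81. The regulatory T cell list had 4 of 6 genes higher (4 adjusted over the list alone; Ctla4 1.61) and the immune checkpoint list 5 of 11 (9 adjusted over the list alone; Pdcd1 1.42, Cd274 1.68, Ido1 2.13). Dendritic cell genes rose in 5 of 11 cases (7 adjusted over the list alone; Irf8 1.53, Itgax 1.60), and chemokines and receptors of lymphocyte traffic in 7 of 16 (8 higher and 1 lower adjusted over the list alone; Cxcr6 1.33), with Cxcl10 lower by a log2 fold change of -1.45. Each of these 8 lists had adjusted p = 0.203 with an estimated correlation. NK cell genes rose in 4 of 8 cases (6 adjusted over the list alone; adjusted p = 0.337 with an estimated correlation), macrophage and monocyte genes in 7 of 17, with Mertk lower (9 and 1 adjusted over the list alone; adjusted p = 0.395 with an estimated correlation) and classically activated myeloid genes in 6 of 14 with 1 lower (6 and 2 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation). Ccl5 had a log2 fold change of 0.43 (SE 0.36, adjusted p = 0.442) and did not pass, and without cryoablation replicate 1 it was 1.00 with adjusted p = 0.0377. Over 16 alternatives, which leave out the fits with Jchain or B and plasma cell genes, its adjusted p ran from 0.0377 to 0.949.

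Erythroid genes and some neutrophil genes fell after cryo-thermal therapy. All 5 measured erythroid genes fell (5 adjusted over the list alone; median -3.32; adjusted p = 0.266 with an estimated correlation), and Hbb-bs, a beta globin, measured 347 ± 81.7 FPKM after cryoablation and 41.0 ± 50.6 after cryo-thermal therapy. Of 13 neutrophil genes 4 fell (5 adjusted over the list alone; adjusted p = 0.513 with an estimated correlation), led by the calprotectin genes S100a9 at -3.65 and S100a8 at -3.29. One gene of liver, the albumin gene Alb, fell by 2.80. The hypoxia and glycolysis list, median 0.24, and the endothelium list, median 0.30, passed with the preset correlation and had adjusted p = 0.62 and adjusted p = 0.656 with an estimated correlation. They held 1 and 0 genes past the limma test, and 0 in each adjusted over the list alone; at unadjusted p under 0.05 the whole comparison held 3910 genes, with 629 expected by chance. Over 12587 genes tested with limma, 1008 were higher and 876 lower at an adjusted p under 0.05, and 251 and 39 of these changed more than 2-fold. The count was 538 without cryoablation replicate 1, 952 without cryoablation replicate 3, 460 without cryo-thermal replicate 1 and 698 without cryo-thermal replicate 2. With the erythroid level as a covariate it was 0, with array weights, which count the more variable tumours less, 5461, and in a fit of only these 2 groups 1037. Of the 17 lists that passed, 6 had a median that moved by over 1.5 times when 1 tumour was left out, and 4 lost their call.

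Cryo-thermal therapy was set against radiofrequency ablation, both without anti-PD-1. With equal weight for every tumour Ccl11, the chemokine eotaxin, was the one gene to pass limma: it rose from 1.08 ± 0.0998 to 5.87 ± 2.62 FPKM (log2 fold change 1.65, SE 0.23, adjusted p = 0.0322). Cxcl14 had a log2 fold change of 1.61, Sh2d4a of 0.60 and Stip1 of 0.36, and on the lower side Ncam1 had -0.58, Zfp821 -0.31 and Klf10 -0.27; none of these passed (adjusted p = 0.155 to 0.262). T cell and interferon genes lay on the higher side without passing over all genes. The T cell list had a median of 0.70, with Cd3d at 1.08 and Cd2 at 1.35 (0 genes past limma over all genes, 9 adjusted over the list alone). Jchain had log2 levels of 2.53, 2.34 and 0.71 in cryo-thermal replicates 1, 2 and 3 and of 0.05, 0.21 and 0.73 in the radiofrequency tumours. For cytotoxic lymphocytes the median was 0.83, with Cd8a at 1.10 and Xcl1 at 1.15 (0 over all genes, 9 adjusted over the list alone), and for the interferon gamma response it was 1.08 with Ido1 at 1.52 (0 over all genes, 1 adjusted over the list alone). The type I interferon list had a median of 0.76 (0 over all genes, 7 adjusted over the list alone), MHC class I presentation 0.55 (0 and 1 adjusted over the list alone), regulatory T cells 0.55 (0 and 4 adjusted over the list alone) and chemokines of lymphocyte traffic 0.82 (0 and 4 higher and 1 lower adjusted over the list alone). These 7 lists passed camera with the preset correlation and had adjusted p = 0.353 with an estimated correlation. Ccl5 had a log2 fold change of 0.92 (adjusted p = 0.305), Ifng of 0.82 (adjusted p = 0.262) and Cxcl10 of -1.64 (adjusted p = 0.262).

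Erythroid genes lay lower after cryo-thermal therapy than after radiofrequency ablation, with a median of -1.72, and skeletal muscle genes higher, with a median of 0.73 and Acta1, skeletal actin, at 1.62; both lists had adjusted p = 0.353 with an estimated correlation. The epithelial and mammary carcinoma list had a median of -0.43 and the endothelium list one of 0.38 (adjusted p = 0.388 for both with an estimated correlation). The first became 0.05 with array weights and -0.01 without radiofrequency replicate 3, and lost its call in both cases. The second ran from 0.21 without radiofrequency replicate 2 to 0.72 without its replicate 3. In all 20 lists passed with the preset correlation, 18 upward and 2 downward, and with an estimated correlation their adjusted p ran from 0.353 to 0.404. Leaving out 1 tumour moved the median of 15 of them by over 1.5 times and ended the call of 8. The erythroid median was -0.61 without radiofrequency replicate 3. At unadjusted p under 0.05, 1712 genes differed, 1039 higher and 673 lower. Without cryo-thermal replicate 3 the count of genes past limma was 278, without radiofrequency replicate 3 it was 5, and without any single one of the other 4 tumours it was 0; it was also 0 with the erythroid level as a covariate, in a fit of only these 2 groups and without the skin-rich tumours, 2 with the keratinocyte level and 1373 with array weights.

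Radiofrequency ablation differed from cryoablation in 1 gene past limma, the clone gene 5430416N02Rik (NCBI gene 100503199), singled out after its values were seen. It rose from 20.2 ± 0.619 to 34.5 ± 0.915 FPKM (log2 fold change 0.75, adjusted p = 0.00394). The genes next by p did not pass. Hsph1, a heat shock chaperone, had a log2 fold change of 0.92, Trib3, a target of the integrated stress response, of 1.62, and Cebpg of 0.51. On the lower side Cirbp, a cold-inducible RNA-binding protein, had -0.64, measuring 44.1 ± 1.19 FPKM after cryoablation and 27.9 ± 2.12 after radiofrequency ablation, and the liver genes Alb and Apoa2 had -2.94 and -1.46 (adjusted p = 0.0995 to 0.106 for these 6). The type I interferon response list had a median of 1.38 with Ifit1 at 1.62 and Rtp4 at 1.44 (0 genes past limma over all genes, 16 adjusted over the list alone). For the interferon gamma response the median was 1.52 with Cxcl9 at 1.72 (0 over all genes, 12 adjusted over the list alone), for MHC class II presentation 1.09 with H2-Aa at 1.44 (0 and 8 adjusted over the list alone) and for MHC class I presentation 0.61 (0 and 4 adjusted over the list alone). Hypoxia and glycolysis had 0.35 with Vegfa at 0.67, cell proliferation -0.21 with Mcm6 at -0.27, oxidative phosphorylation -0.09 and fibroblasts and matrix -0.26, with 0 genes in each past limma and, adjusted over the list alone, 1 lower in cell proliferation and 0 in the other lists. All 8 had adjusted p = 0.604 with an estimated correlation. Erythroid genes had a median of -1.53, with levels in the 3 radiofrequency tumours spread from 2.47 to 6.82 as mean log2 values (adjusted p = 0.604 with an estimated correlation). That median was -0.24 without radiofrequency replicate 2 and -2.50 without its replicate 3. In all 15 lists passed with the preset correlation. When 1 tumour was left out, 10 of their medians moved by over 1.5 times and 9 lists lost their call. At unadjusted p under 0.05 there were 1902 genes. The gene count was 20 without cryoablation replicate 2, and 9 without the skin-rich tumours, none of which is in these groups but which enter the shared estimate of the spread. With array weights it was 571 and without a filter on low values 3. Ccl5 had a log2 fold change of -0.49 (adjusted p = 0.53).

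With anti-PD-1 given to both groups, cryo-thermal therapy was compared with cryoablation. Interferon gamma targets and cytotoxic genes rose. Ido1, which degrades tryptophan, went from 1.73 ± 2.37 to 10.4 ± 1.66 FPKM (log2 fold change 2.39, SE 0.43, adjusted p = 0.0159), and Nos2, the inducible nitric oxide synthase of activated macrophages, from 3.64 ± 2.82 to 20.2 ± 3.94 FPKM (2.34, SE 0.45, adjusted p = 0.0181). Gzmb rose by 2.31, Ifng by 1.66, Cd8a by 1.63 and Ccl5 by 1.42 (adjusted p = 0.0404), while Cxcl10 had -0.18 (adjusted p = 0.859). Chil3, a chitinase-like protein of myeloid cells, had the largest change, from 6.11 ± 0.78 to 98.5 ± 51.2 FPKM, followed by Ubd, a ubiquitin-like modifier, at 2.96, and the serpin Serpina3f at 2.82. Among genes that fell were Fcrl2 at -2.22, Cbr2 at -2.17, the macrophage lectin Cd209f at -2.02 and Cavin2, a caveolar coat protein, at -1.06.

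By list, 12 of 17 interferon gamma response genes rose (17 adjusted over the list alone; median 1.86), 12 of 14 cytotoxic lymphocyte genes (14 adjusted over the list alone; median 1.53), 12 of 16 genes of MHC class I presentation (16 adjusted over the list alone; Tap2 1.24) and 6 of 8 NK cell genes (7 adjusted over the list alone; Prf1 1.63). The immune checkpoint list had 7 of 11 higher (9 adjusted over the list alone; Pdcd1lg2 1.77, Cd274 1.68), regulatory T cells 2 of 6 (5 adjusted over the list alone; Il2ra 0.66) and classically activated myeloid genes 3 of 14 (9 adjusted over the list alone; Cd40 1.00). Each of these had adjusted p = 0.192 with an estimated correlation. T cell genes rose in 7 of 12 cases (10 adjusted over the list alone; Cd3d 1.29) and MHC class II presentation in 7 of 8 (7 adjusted over the list alone; Cd74 1.76), both with adjusted p = 0.209 with an estimated correlation. The type I interferon response had 0 of 18 genes past limma and 0 adjusted over the list alone, with a median of 0.60 (adjusted p = 0.551 with an estimated correlation). Skeletal muscle genes lay lower, median -1.03, with 0 of 13 over all genes and 6 adjusted over the list alone (Ckm -1.51; adjusted p = 0.386 with an estimated correlation). In all 16 lists passed with the preset correlation, and with an estimated correlation their adjusted p ran from 0.192 to 0.613. With 1 tumour left out the medians of 5 moved by over 1.5 times and 4 lost their call. The keratinocyte level, in mean log2 units, was 2.61, 2.25 and 1.56 in the 3 cryoablation tumours and 3.51, 1.86 and 0.026 in the 3 cryo-thermal tumours.

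In this comparison 408 genes were higher and 103 lower with limma, 79.8% higher, and with quantile normalization 292 were higher and 144 lower, 67.0% higher. At unadjusted p under 0.05 there were 2605 genes. The count was 2 without cryoablation plus anti-PD-1 replicate 2, 2 without its replicate 3, 1052 without its replicate 1, 3 without cryo-thermal plus anti-PD-1 replicate 2, 17 without its replicate 3 and 0 in a fit of only these 2 groups. It was 329 without the 3 skin-rich tumours, 339 with the keratinocyte level as a covariate and 1049 with the erythroid level, 4156 with array weights and 180 without a filter, and the Ccl5 call was lost without any one of cryoablation plus anti-PD-1 replicates 1, 2 and 3 (adjusted p = 0.0566, 0.142 and 0.129) or of cryo-thermal plus anti-PD-1 replicates 2 and 3 (adjusted p = 0.157 and 0.152). Over all alternatives the adjusted p of Ccl5 ran from 0.000688 to 0.22.

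Against radiofrequency ablation plus anti-PD-1, cryo-thermal therapy plus anti-PD-1 again gave higher Ido1 (log2 fold change 2.59, SE 0.43, adjusted p = 0.0189) and Nos2 (2.04, adjusted p = 0.0451). Cd8a rose by 1.66 and Cd8b1 by 1.40, the 2 chains of CD8, and Ifng rose by 1.34 (adjusted p = 0.0362). The cytokine receptor genes Il12rb1 and Il18rap rose by 1.59 and 1.27, and Ass1, which makes the arginine precursor used by nitric oxide synthase, rose from 10.8 ± 1.87 to 34.4 ± 8.88 FPKM. Egr1, an immediate early transcription factor, fell from 113 ± 51.7 to 22.3 ± 6.72 FPKM, and Fcrl2, Cd209f and Cavin2 fell by 2.43, 1.56 and 0.85. Ccl5 had a log2 fold change of 1.3 (adjusted p = 0.0859), Gzmb of 1.04 (adjusted p = 0.27) and Cxcl10 of -1.50 (adjusted p = 0.0926), none of which passed.

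Over all genes 4 of 14 cytotoxic lymphocyte genes rose (10 adjusted over the list alone), 1 of 12 T cell genes (8 adjusted over the list alone), 1 of 17 interferon gamma response genes (9 adjusted over the list alone) and 1 of 11 immune checkpoint genes (8 adjusted over the list alone). MHC class I presentation had 0 past limma and 15 of 16 adjusted over the list alone (median 0.83), and MHC class II presentation 0 and 7 of 8 adjusted over the list alone (median 1.08). Skeletal muscle genes lay lower with a median of -1.18, 0 of 13 over all genes and 10 adjusted over the list alone (Atp2a1 -1.14). All 7 lists had adjusted p = 0.318 with an estimated correlation. Keratinocyte genes had a median of 0.71 (adjusted p = 0.676 with an estimated correlation), which became -0.19 without cryo-thermal plus anti-PD-1 replicate 1 and 1.65 without its replicate 3. Of the 27 lists 16 passed with the preset correlation, and with an estimated correlation their adjusted p ran from 0.318 to 0.751. Leaving out 1 tumour moved the medians of 7 lists by over 1.5 times and ended the call of 7. In all 103 genes were higher and 62 lower with limma, and 2162 had an unadjusted p under 0.05. The count was 79 without radiofrequency plus anti-PD-1 replicate 1, 2 without its replicate 2, 22 without its replicate 3, 0 without cryo-thermal plus anti-PD-1 replicate 2 and 1 without its replicate 3. It was 488 with the erythroid level as a covariate, 96 with the keratinocyte level, 2154 with array weights, 71 in a fit of only these 2 groups, 74 without a filter, 88 with a pseudocount of 0.1 and 64 after rescaling each tumour to the same FPKM sum.

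Radiofrequency ablation plus anti-PD-1 and cryoablation plus anti-PD-1 differed in 0 genes with limma. The smallest adjusted p was 0.729, and 736 genes had an unadjusted p under 0.05 against 629 expected by chance; without a filter 1 gene passed. Granzymes made by lymphocytes were among the genes with the smallest p: Gzmc measured 33.0 ± 20.7 against 9.55 ± 3.97 FPKM (log2 fold change 1.59) and Gzmf 68.0 ± 49.4 against 16.4 ± 8.13 FPKM (1.88). Bcl3 had 0.48, Atosa -0.61 and Inhba -0.65. The interferon gamma response list had a median of 0.73 and the type I interferon list one of 0.47, with 0 genes in each adjusted over the list alone, and cytotoxic lymphocytes one of 0.36 with 3 (Prf1 1.23). Skin keratinocyte genes had a median of -1.05 with 2 of 12 lower adjusted over the list alone, the hair root sheath keratins Krt71 at -2.45 and Krt25 at -2.06, mast cell genes -0.43 and endothelium -0.15. The keratinocyte median ran from -1.49 without radiofrequency plus anti-PD-1 replicate 1 to -0.51 without its replicate 3, and was -0.49 without the skin-rich tumours and 0.17 with the keratinocyte level as a covariate. That of endothelium turned to 0.08 without radiofrequency plus anti-PD-1 replicate 3 and to 0.08 with that covariate. For mast cells it was -0.16 without that tumour. Each of the 12 lists that passed with the preset correlation had adjusted p = 0.797 with an estimated correlation. The median of each moved by over 1.5 times when 1 tumour was left out, and 11 lost their call. Ccl5 had a log2 fold change of 0.13 and Cxcl10 of 1.33 (adjusted p = 0.978 and 0.824).

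With anti-PD-1 added to cryoablation, erythroid genes fell in 3 of 5 cases. Chac1, Gdf15, Trib3 and Aldh1l2, each a known target of the integrated stress response, for which no list was fixed, rose by 1.57, 1.55, 1.52 and 1.46. Gdf15 went from 3.19 ± 1.7 to 10.8 ± 1.79 FPKM (adjusted p = 0.0259). Mean Trib3 was 6.50 FPKM after cryoablation and 20.2 with anti-PD-1. It was already 21.5 and 22.0 FPKM without the antibody after radiofrequency ablation and cryo-thermal therapy, so cryoablation alone was the low group. Cdsn, a protein of cornified skin, rose from 2.08 ± 1.15 to 12.3 ± 1.29 FPKM (log2 fold change 2.17, SE 0.32, adjusted p = 0.0112), and Cd209f and the chemokine Ccl8 by 1.97 and 1.81. The globins Hbb-bt and Hba-a2 fell by 3.74 and 3.46, Alas2, which starts haem synthesis, by 2.49, Chil3 by 2.99 and the neutrophil chemokine Cxcl1 by 1.99. Of 5 erythroid genes 3 fell (5 adjusted over the list alone; median -3.28), and keratinocyte genes lay higher with a median of 1.14 and 0 adjusted over the list alone, as did skeletal muscle genes with a median of 0.95 and 9 of 13 adjusted over the list alone. The type I interferon response had 2 of 18 genes past limma, Oasl1 at 1.13 and Oas1a at 1.46 (13 adjusted over the list alone), the interferon gamma response 0 of 17 (0 adjusted over the list alone; median 1.05), MHC class II presentation 0 of 8 (6 adjusted over the list alone; median 0.94, but 0.52 without cryoablation plus anti-PD-1 replicate 1 and -0.09 with the erythroid level as a covariate) and T cells 0 of 12 (1 adjusted over the list alone; Cd4 0.75). Mast cell genes had a median of 0.97, adipose genes 0.56, epithelial genes 0.48 and neutrophil genes -1.11. Each list named here had adjusted p = 0.507 with an estimated correlation. Of the 17 lists that passed with the preset correlation, 11 had a median that moved by over 1.5 times when 1 tumour was left out and 9 lost their call. The interferon gamma median was 0.41 without cryoablation plus anti-PD-1 replicate 1.

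With limma, 225 genes were higher and 318 lower in that comparison, and 3071 had an unadjusted p under 0.05. The count was 0 without cryoablation replicate 1, 20 without cryoablation replicate 3, 7, 339 and 205 without cryoablation plus anti-PD-1 replicates 1, 2 and 3, 0 with the erythroid level as a covariate, 0 without the skin-rich tumours, which leaves 1 tumour with anti-PD-1 that is assumed to vary like the other groups, and 148 with the keratinocyte level. It was 1974 with array weights, 140 without a filter and 327 after rescaling. Of the 11 genes chosen in advance none passed: Ccl5 had a log2 fold change of -0.71 (adjusted p = 0.243), Cd8a of 0.81 (adjusted p = 0.158) and Ifng of 0.37 (adjusted p = 0.409).

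With anti-PD-1 added to radiofrequency ablation, 6 genes differed with limma. Thbs4, a thrombospondin of muscle and tendon, rose from 3.86 ± 1.4 to 20.1 ± 4.41 FPKM (log2 fold change 2.14, SE 0.33, adjusted p = 0.037). Ccl11 rose by 1.45, the lectin gene Cd209g by 1.09 and Cad, an enzyme of pyrimidine synthesis, by 0.36, and Ccng2, a cyclin linked to arrest, and Dnase1l1 fell by 0.57 and 0.34. Skeletal muscle genes lay higher, with Acta1 at 2.97, Tnnc2 at 2.45 and a median of 1.57; 0 of 13 passed over all genes and 12 adjusted over the list alone (adjusted p = 0.511 with an estimated correlation). Hypoxia and glycolysis genes had a median of -0.30 with Ankrd37 at -0.84 (0 and 4 lower adjusted over the list alone), proliferation genes 0.21 with Mcm2 at 0.32 (0 and 4 higher adjusted over the list alone), regulatory T cell genes 0.40 with Ctla4 at 1.03 (0 and 2 adjusted over the list alone) and erythroid genes -1.68 (0 and 0 adjusted over the list alone; -0.67 without radiofrequency replicate 3). Immediate early and heat shock genes had a median of 0.32 with Fosb at 2.16 (0 and 1 adjusted over the list alone). These 5 lists had adjusted p = 0.719 with an estimated correlation. Of all 9 that passed, 6 had a median that moved by over 1.5 times and 7 lost their call when 1 tumour was left out. Of the 6 genes 66.7% were higher, and after rescaling each tumour to the same FPKM sum 3 genes passed, 100% of them higher. The count was 0, 2 and 1 without radiofrequency replicates 1, 2 and 3, 0, 0 and 3 without radiofrequency plus anti-PD-1 replicates 1, 2 and 3, and 0 with the erythroid level as a covariate or without the skin-rich tumours. It was 13 with the keratinocyte level, 10 without a filter and 1 in a fit of only these 2 groups. At unadjusted p under 0.05 there were 1457 genes. Ccl5 had a log2 fold change of -0.09, Cd8a of 0.05 and Cxcl10 of 0.90 (adjusted p = 0.435 to 0.967).

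With anti-PD-1 added to cryo-thermal therapy, 31 genes rose and 16 fell with limma. Cavin2 fell from 16.2 ± 0.955 to 5.75 ± 0.442 FPKM (log2 fold change -1.35, SE 0.14, adjusted p = 0.000744) together with Cav1, caveolin-1, at -0.65. Cdh1, the epithelial cadherin, rose from 2.09 ± 0.294 to 4.96 ± 0.308 FPKM (0.95, SE 0.11, adjusted p = 0.00136). Chil3 rose by 3.70 and the chemokine Ccl24 by 1.82, and Nt5e, the ectonucleotidase CD73, went from 7.32 ± 1.07 to 16.4 ± 2.05 FPKM. Ogn, the matrix proteoglycan osteoglycin, fell by 1.94, and the ferritin receptor gene Scara5 by 1.24. Interferon gamma response genes had a median of 0.54 (0 of 17 past limma, 0 adjusted over the list alone), cytotoxic lymphocytes 0.49 with Ifng at 0.98 (0 and 1 adjusted over the list alone), neutrophils 0.38 with S100a9 at 2.87 (0 and 3 adjusted over the list alone) and immune checkpoints 0.34 with Pdcd1lg2 at 1.51 (0 and 1 adjusted over the list alone). The type I interferon list had -0.32, hypoxia and glycolysis -0.25 with Car9 at -1.16, and immediate early and heat shock genes -0.30 with Egr1 at -1.73. Keratinocyte genes had a median of 1.10, with 0 adjusted over the list alone, and epithelial genes 0.90, with Cdh1 the 1 gene adjusted over the list alone. Without cryo-thermal plus anti-PD-1 replicate 1, a skin-rich tumour, these medians were 0.29 and 0.30, and with the keratinocyte level as a covariate -0.06 and 0.10. Each of these 9 lists had adjusted p = 0.712 with an estimated correlation. In all 14 passed with the preset correlation, and leaving out 1 tumour moved the medians of 10 by over 1.5 times and ended the call of 11. None of the 11 genes chosen in advance passed: Ccl5 had 0.29 (adjusted p = 0.77), Cd8a 0.61 (adjusted p = 0.458) and Cxcl9 1.15 (adjusted p = 0.331).

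At unadjusted p under 0.05 that comparison held 1631 genes. The count of 47 was 80, 10 and 22 without cryo-thermal replicates 1, 2 and 3, and 2 and 12 without cryo-thermal plus anti-PD-1 replicates 2 and 3. It was 1 in a fit of only these 2 groups, 5 without the skin-rich tumours, 106 with the erythroid level as a covariate and 5332 with array weights.

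Whether the effect of anti-PD-1 differed between ablations was tested as a difference of differences. Against cryoablation 21 genes differed with limma, 14 with a more positive effect after cryo-thermal therapy and 7 with a more negative one. Chil3 fell with anti-PD-1 after cryoablation and rose with it after cryo-thermal therapy, a difference of 6.68 (SE 0.97, adjusted p = 0.013). Cavin2 differed by -1.43, Rgs2, a regulator of G protein signalling, by -1.05, Plxnb1, a semaphorin receptor, by 1.19 and Azin2, an inhibitor of antizyme, by 1.15 (adjusted p = 0.0103 to 0.013). Erythroid genes differed by a median of 4.68 (0 of 5 past limma, 5 adjusted over the list alone), neutrophil genes by 1.43 (0 and 4 adjusted over the list alone) and type I interferon genes by -1.35 (0 and 10 lower adjusted over the list alone), each with adjusted p = 0.638 with an estimated correlation. Ccl5 differed by 0.99 (adjusted p = 0.418) and Ifng by 0.61 (adjusted p = 0.488). At unadjusted p under 0.05 there were 1687 genes. The count was 1, 52 and 0 without cryoablation replicates 1, 2 and 3, 11, 8 and 3 without cryoablation plus anti-PD-1 replicates 1, 2 and 3, 12, 7 and 189 without cryo-thermal replicates 1, 2 and 3, 8, 7 and 10 without cryo-thermal plus anti-PD-1 replicates 1, 2 and 3, 0 with the erythroid level as a covariate, 36 with the keratinocyte level, 1 without the skin-rich tumours and 2636 with array weights.

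Against radiofrequency ablation 0 genes differed in their anti-PD-1 effect with limma (smallest adjusted p = 0.14), and 910 had an unadjusted p under 0.05. Skeletal muscle genes differed by a median of -1.94 (0 of 13 past limma, 12 lower adjusted over the list alone; adjusted p = 0.458 with an estimated correlation), and erythroid genes by 2.89 (0 and 3 adjusted over the list alone; adjusted p = 0.669 with an estimated correlation). Ccl5 differed by 0.37, Cxcl9 by 1.43 and Ifng by 0.52 (adjusted p = 0.703 to 0.925). With array weights the count was 375, without cryo-thermal replicate 3 it was 4, without a filter 2, and without the skin-rich tumours or in a fit of only these groups 1.

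Averaged over the 3 ablations, 8 of 13 skeletal muscle genes and 3 of 12 T cell genes rose with anti-PD-1. The muscle rise was not shared by all 3: the median was 0.95 after cryoablation, 1.57 after radiofrequency ablation and -0.27 after cryo-thermal therapy, where the list did not pass (adjusted p = 0.0915 with the preset correlation). Des, the muscle filament desmin, rose by a log2 fold change of 1.17 (SE 0.17, adjusted p = 0.00407), Acta1 by 1.66 and Mb, myoglobin, by 0.89 (12 muscle genes adjusted over the list alone). The T cell genes (11 adjusted over the list alone) were Cd4, which rose by 0.55, Cd2 by 0.78 and Cd6 by 0.40. Ifng rose by 0.60 (adjusted p = 0.0223). Of the regulatory T cell list Il2ra and Ctla4 rose by 0.33 and 0.71 (2 of 6; 4 adjusted over the list alone), of the immune checkpoint list Pdcd1lg2 and Ctla4 (2 of 11; 4 adjusted over the list alone), of the dendritic list Itgax and Ccl22 by 0.78 and 0.57 (2 of 11; 4 adjusted over the list alone) and of the alternatively activated myeloid list Cd209f, Ccl24 and Tgfb1 by 1.07, 0.84 and 0.16 (3 of 14; 3 adjusted over the list alone). Such an average does not show that each ablation shared a rise. Mean Ccl24 went from 1.15 to 1.18 FPKM with anti-PD-1 after cryoablation and from 0.358 to 3.995 FPKM after cryo-thermal therapy. The fractalkine receptor gene Cx3cr1 fell by 0.79. The interferon gamma response had 0 of 17 past limma and 16 adjusted over the list alone (median 0.66). Epithelial genes rose in 1 of 7 cases, Cdh1 by 0.48 (1 adjusted over the list alone), keratinocyte genes had a median of 0.92 (0 and 0 adjusted over the list alone) and erythroid genes one of -1.25 (0 and 4 lower adjusted over the list alone). The erythroid median also differed by ablation, with -3.28, -1.68 and 1.22 after cryoablation, radiofrequency and cryo-thermal therapy. Each of these lists had adjusted p = 0.527 with an estimated correlation. Hypoxia and glycolysis genes fell in 3 of 18 cases, Ankrd37 by 0.55, Pdk1 by 0.31 and Car9 by 0.65 (4 adjusted over the list alone), and proliferation genes rose in 2 of 20, Mcm2 and Mcm5 by 0.19 and 0.24 (4 adjusted over the list alone), both with adjusted p = 0.563 with an estimated correlation. Ccl5 had -0.17 (adjusted p = 0.627) and Cd8a 0.49 (adjusted p = 0.113).

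In that averaged comparison 664 genes were higher and 598 lower with limma, 14 and 4 of them by more than 2-fold, and 3584 had an unadjusted p under 0.05. The count was 678 without cryoablation replicate 1, 738 without cryoablation plus anti-PD-1 replicate 1, 762 without radiofrequency replicate 3, 693 without cryo-thermal replicate 3 and 754 without cryo-thermal plus anti-PD-1 replicate 2. It was 35 with the erythroid level as a covariate, 542 with the keratinocyte level, 199 without the skin-rich tumours, 2626 with array weights and 752 without a filter. Of the 18 lists that passed, 8 had a median that moved by over 1.5 times and 4 lost their call when 1 tumour was left out. Across 12587 genes the anti-PD-1 effects after cryoablation and after radiofrequency ablation, which share no tumour, had Pearson r = 0.541 and Spearman rho = 0.452. For cryoablation and cryo-thermal therapy these were 0.217 and 0.236, and for radiofrequency and cryo-thermal therapy 0.131 and 0.306. Genes are not independent replicates.

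Averaged over anti-PD-1, cryo-thermal therapy was compared with the mean of the other 2 ablations, 6 tumours against 12. Ido1 rose by a log2 fold change of 2.16 (SE 0.26, adjusted p = 0.00145), Cd8a by 1.56, Gzmb by 1.37, Cd274 by 1.31, Ifng by 1.21 and Pdcd1 by 1.17. Ccl5 rose by 1.02 (SE 0.22, adjusted p = 0.00716), Itgam, the CD11b chain of myeloid cells, by 0.39, and Cxcl9 by 1.05, whereas Cxcl10 fell by 1.19 (adjusted p = 0.00812). Among the genes whose values did not overlap, Igtp led at 2.09, followed by Xcl1 at 1.26 and Tapbp, the tapasin of peptide loading, at 0.91, and the neural adhesion gene Ncam1 fell by 0.58 and Egr3 by 0.50.

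All 17 interferon gamma response genes rose (17 adjusted over the list alone; median 1.63), as did all 16 of MHC class I presentation (16 adjusted over the list alone; median 0.92), 7 of 8 of MHC class II presentation (8 adjusted over the list alone; median 1.36), 11 of 12 T cell genes (11 adjusted over the list alone; Lck 1.26), 12 of 14 cytotoxic lymphocyte genes (14 adjusted over the list alone; Nkg7 1.73), 5 of 6 regulatory T cell genes (5 adjusted over the list alone) and 9 of 11 immune checkpoint genes (11 adjusted over the list alone). Classically activated myeloid genes rose in 9 of 14 cases (10 higher and 1 lower adjusted over the list alone; Nos2 1.55, Cd40 0.77) with Cxcl10 lower, and chemokines of lymphocyte traffic in 8 of 16 (11 higher and 2 lower adjusted over the list alone; Cxcr6 1.13). Each of these 9 lists had adjusted p = 0.156 with an estimated correlation. With the Jchain level as a covariate 0 of 12 T cell genes passed limma, and the T cell median went from 0.85 to 0.38. NK cell genes rose in 7 of 8 cases (7 adjusted over the list alone; adjusted p = 0.183 with an estimated correlation) and type I interferon genes in 17 of 18 (18 adjusted over the list alone; median 0.92; adjusted p = 0.221 with an estimated correlation). Gzmb and Prf1 of the NK cell list are also in the cytotoxic list, so its rise is not separate evidence of NK cells. Macrophage and monocyte genes rose in 9 of 17 cases (12 adjusted over the list alone; Ctss 0.92), with the efferocytosis receptor gene Mertk at -0.50 (adjusted p = 0.353 with an estimated correlation). Of 19 genes of fibroblasts and matrix 4 fell (9 adjusted over the list alone), Fn1 by 0.74 and Col3a1 by 0.75 among them (adjusted p = 0.664 with an estimated correlation). Erythroid genes had a median of -0.63, skeletal muscle genes -0.27 and keratinocyte genes 0.07, and none of these 3 lists passed (adjusted p = 0.203, 0.203 and 0.932 with the preset correlation).

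With limma 1326 genes were higher and 917 lower, 59.1% higher, and with quantile normalization 1152 were higher and 1339 lower, 46.2% higher. By more than 2-fold 114 rose and 6 fell, and 4197 genes had an unadjusted p under 0.05. The count was 1105 without cryo-thermal replicate 1, 1332 without its replicate 2, 1331 without cryo-thermal plus anti-PD-1 replicate 2, 1311 without its replicate 3, 1300 with the erythroid level as a covariate and 6173 with array weights. Of the 16 lists that passed, 2 had a median that moved by over 1.5 times and 3 lost their call when 1 tumour was left out. The adjusted p of Ccl5 stayed between 0.00019 and 0.0258 over 27 alternatives. These leave out the fit with the Jchain level as a covariate, in which 0 genes passed limma, so Ccl5 lost its call there.

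**Figure D2:**
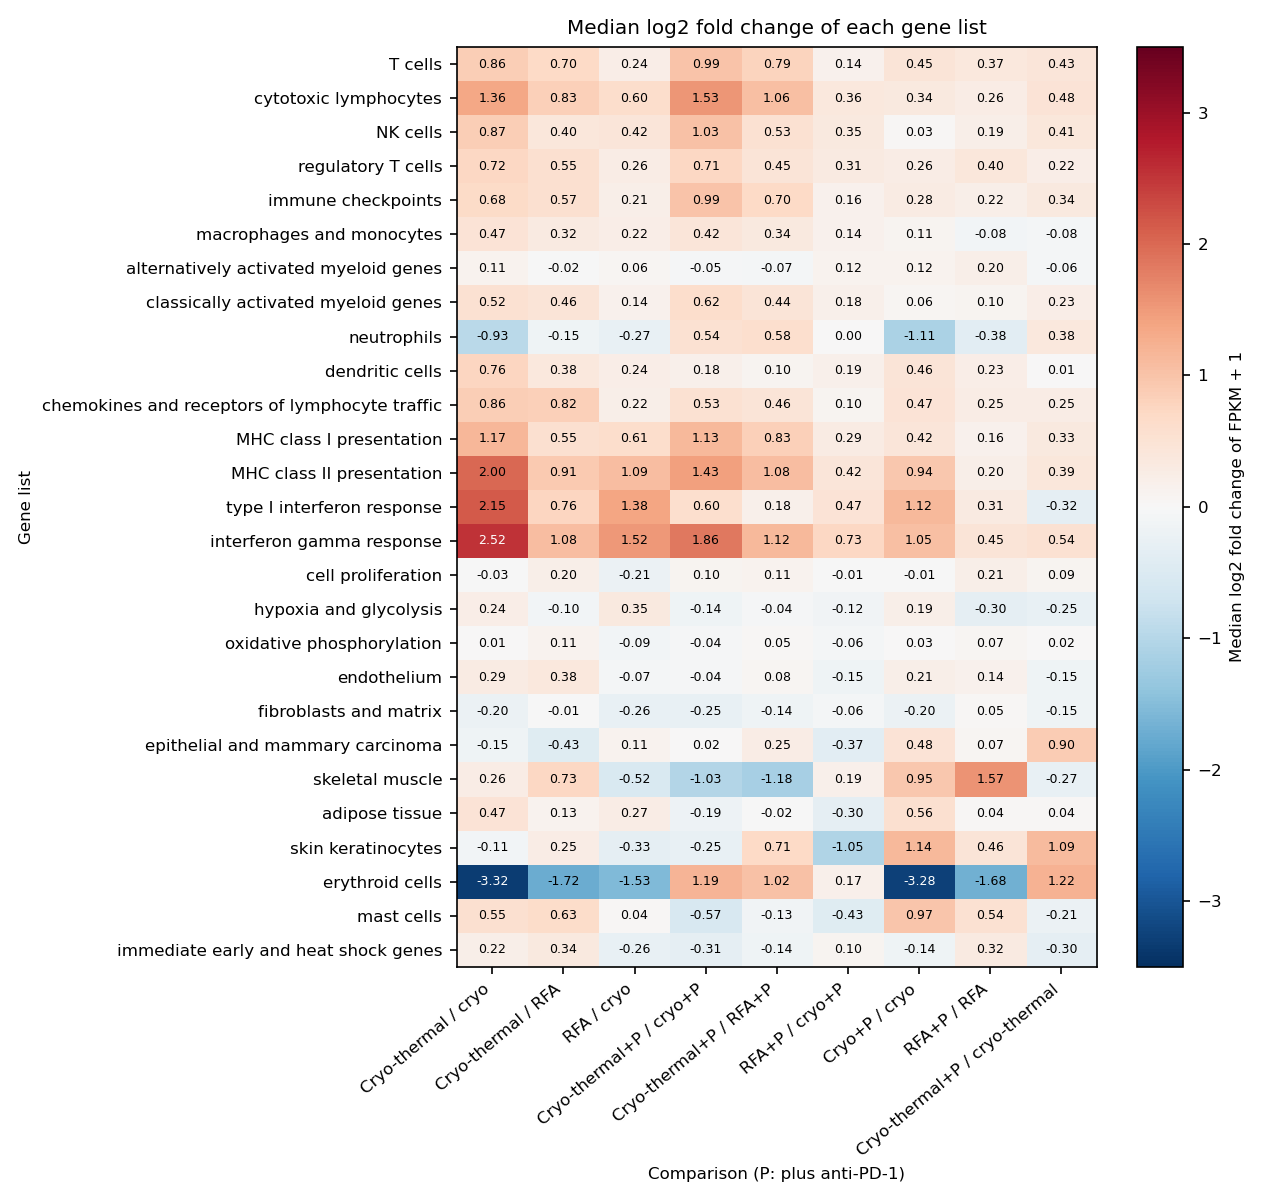
Median log2 fold change, on the log2(FPKM + 1) scale, of the genes of each of 27 lists (vertical) in each of the 9 comparisons between 2 groups (horizontal; RFA, radiofrequency ablation; P, anti-PD-1), as a heat map with the value in each cell. The interferon gamma response list stands at 2.52 for cryo-thermal therapy against cryoablation and at 1.86 with anti-PD-1 in both, and the erythroid list at -3.32 and 1.19.

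**Figure D3:**
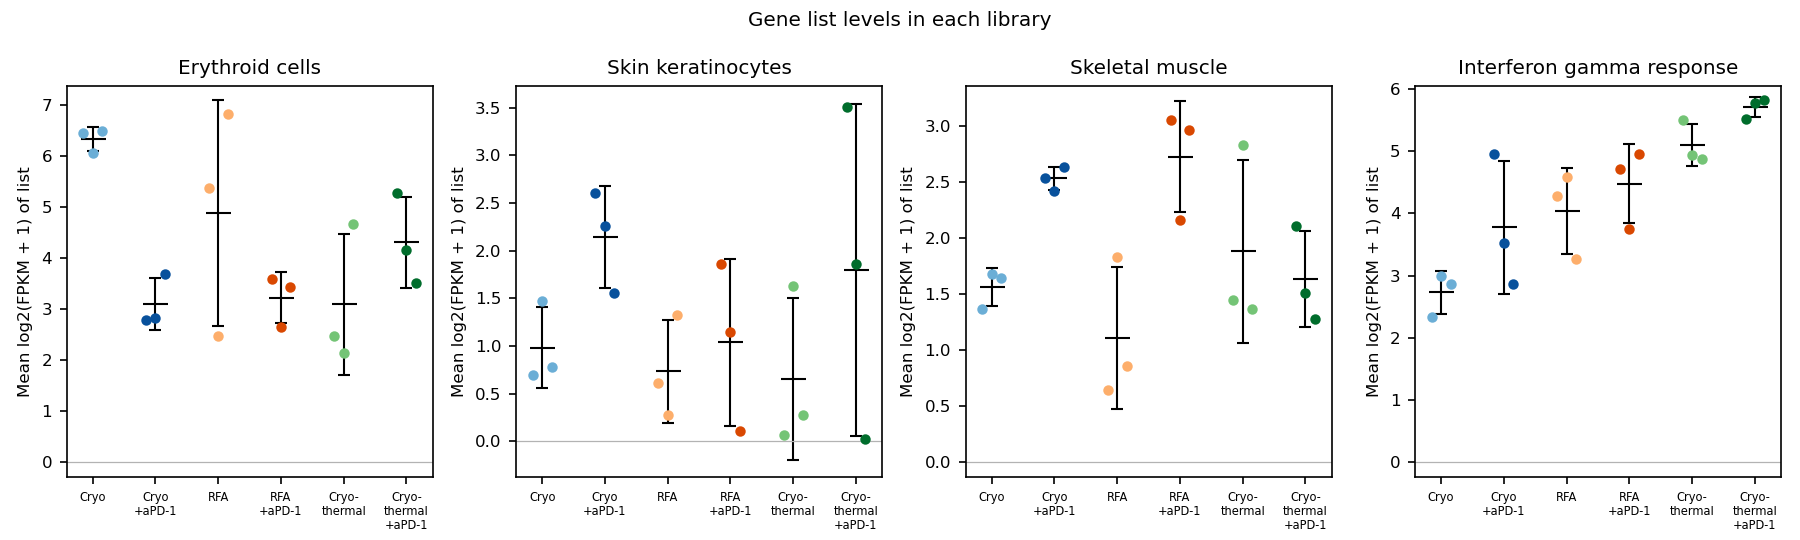
Mean log2(FPKM + 1) of the erythroid, skin keratinocyte, skeletal muscle and interferon gamma response lists in each of the 18 tumours by treatment (Cryo, cryoablation; RFA, radiofrequency ablation; aPD-1, antibody against PD-1). Points are tumours, the black dash is the mean of 3 and the bars are 1 SD; erythroid levels lay between 6.05 and 6.49 in the 3 cryoablation tumours and between 2.80 and 3.68 after cryoablation plus anti-PD-1.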

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

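The tests in this part were planned, except the fit with the erythroid level as a covariate, which was chosen after the results were seen. The anti-PD-1 effect differed between cryo-thermal therapy and cryoablation in 21 genes by a test of the difference itself. Chil3, the chitinase-like protein of myeloid cells, differed by 6.68, Plxnb1 by 1.19 and Azin2 by 1.15, while Cavin2 differed by -1.43 and Rgs2 by -1.05. Of 100 regroupings of the same tumours 5 gave as many genes, the real one included, so chance was not excluded. The highest other regrouping gave 589 genes, and the source of this count was not tested. Regroupings mix tumours with and without anti-PD-1, so the mean effect of the antibody can enter. With the erythroid level as a covariate 0 genes passed limma against 21 without it, and 1334 against 1687 had an unadjusted p under 0.05. With it Chil3 differed by 7.50 (SE 1.35, from 0.97 without it), Cavin2 by -1.60 (SE 0.27, from 0.20), Rgs2 by -1.18, Azin2 by 1.3 and Plxnb1 by 1.02, with adjusted p = 0.0701 to 0.14, so these calls ended with wider errors.

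In the same comparison 9 lists passed camera with the preset correlation and none of them with an estimated correlation (adjusted p = 0.638 to 0.87). Their medians were 4.68 for erythroid cells, 1.43 for neutrophils, -0.38 for dendritic cells, -1.35 for the type I interferon response, -0.37 for hypoxia and glycolysis, -0.33 for endothelium, -1.26 for skeletal muscle, -1.22 for mast cells and -1.01 for immediate early and heat shock genes.

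Between cryo-thermal therapy and radiofrequency ablation the anti-PD-1 effect differed in 6 lists with the preset correlation and in none with an estimated one (adjusted p = 0.458 to 0.832). Their medians were 2.89 for erythroid cells, 0.68 for neutrophils, 0.82 for epithelial and mammary carcinoma genes, -0.72 for the type I interferon response, -1.94 for skeletal muscle and -0.50 for immediate early and heat shock genes. No single gene passed limma, and 910 had an unadjusted p under 0.05. With a real count of 0 the regroupings decide nothing here; the highest of them gave 135 genes. No biological explanation was tested for the results in this part.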

How the results depend on the processing

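The covariates, the fits without skin-rich tumours and fry were chosen after the results were seen; the other alternatives were planned. Tests for count data were not run because the table holds FPKM, and fits of only the groups compared gave no separate value for the averaged comparisons. Of 321 gene calls among 914 named values, the number that held was 311 with quantile normalization, 299 after rescaling, 297 with a pseudocount of 0.1, 201 without a filter, 317 with array weights, 267 with the keratinocyte covariate, 177 with the erythroid covariate and 224 without skin-rich tumours, and fits of only the groups compared held 107 of 208. Array weights also gave 269 calls of named values that the main fit did not call, and the erythroid covariate gave 27. The weights are estimated from the same tumours, and whether they call too many genes was not tested. When 1 tumour was left out, 2544 of 3312 gene calls and 1245 of 1428 list calls held. Of 170 list calls with the preset correlation 0 held with an estimated correlation and 35 with fry, 12 of them for cryo-thermal therapy against cryoablation, 10 for the same with anti-PD-1 in both and 13 for cryo-thermal therapy against the mean of the other ablations. No call of a named gene and none of the 170 list calls turned direction with quantile normalization, rescaling, a pseudocount of 0.1 or no filter. The depth of about 38100000 fragments was nearly even over tumours, and the causes of the changes below were not tested unless stated.

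Counts of genes past limma when 1 tumour was left out ran from 460 to 2681 for cryo-thermal therapy against cryoablation (A-C below), from 0 to 278 for cryo-thermal against radiofrequency (A-R), from 1 to 20 for radiofrequency against cryoablation (R-C), from 2 to 1052, 0 to 120 and 0 to 0 for the same pairs with anti-PD-1 in both (A-C, A-R and R-C with antibody). They ran from 0 to 452 for anti-PD-1 after cryoablation, from 0 to 3 after radiofrequency, from 2 to 80 after cryo-thermal therapy, from 0 to 189 for the difference of effects against cryoablation, from 0 to 4 for that against radiofrequency, from 678 to 1688 for the mean anti-PD-1 effect and from 1105 to 3003 for cryo-thermal therapy against the mean of the others. Leaving out a tumour also leaves fewer samples.

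With array weights the counts were 5461 for A-C, 1373 for A-R, 571 for R-C, 4156 for A-C with antibody, 2154 for A-R with antibody, 1974 for anti-PD-1 after cryoablation, 5332 after cryo-thermal therapy, 2636 and 375 for the differences of effects against cryoablation and radiofrequency, 2626 for the mean anti-PD-1 effect and 6173 for cryo-thermal therapy against the mean of the others. In fits of only the groups compared, which have fewer samples, they were 1037 for A-C, 0 for A-R, 0 and 71 for A-C and A-R with antibody, 1 for anti-PD-1 after radiofrequency, 1 after cryo-thermal therapy and 1 for the difference against radiofrequency.

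With the erythroid level as a covariate the counts were 0 for A-C, 0 for A-R, 1049 and 488 for A-C and A-R with antibody, 0 for anti-PD-1 after cryoablation, 0 after radiofrequency, 106 after cryo-thermal therapy, 0 for the difference against cryoablation, 35 for the mean anti-PD-1 effect and 1300 for cryo-thermal therapy against the mean of the others. With the keratinocyte level they were 2 for A-R, 339 and 96 for A-C and A-R with antibody, 148 for anti-PD-1 after cryoablation, 13 after radiofrequency, 36 for the difference against cryoablation and 542 for the mean effect. Without skin-rich tumours, which leaves 1 tumour in a group that is assumed to vary like the others, they were 0 for A-R, 9 for R-C, 329 for A-C with antibody, 0, 0 and 5 for anti-PD-1 after cryoablation, radiofrequency and cryo-thermal therapy, 1 and 1 for the differences and 199 for the mean effect.

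Without a filter the counts were 3 for R-C, 180, 74 and 1 for A-C, A-R and R-C with antibody, 140 and 10 for anti-PD-1 after cryoablation and radiofrequency, 2 for the difference against radiofrequency and 752 for the mean effect. A pseudocount of 0.1 gave 88 for A-R with antibody, and rescaling gave 64 there, 327 for anti-PD-1 after cryoablation and 3 after radiofrequency.

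The replicate numbers were not treated as pairs, because no comparison had every tumour closest to its own number. In A-R with antibody deviations of same-number tumours correlated at 0.502, 0.058 and 0.591, with 5 of 6 tumours closest to their own number and fewer elsewhere. A structure shared by number was therefore not excluded there. With a replicate block 281 of the 321 gene calls held. The counts were 0 for A-R, 69 for A-R with antibody, 0 for anti-PD-1 after radiofrequency and 9 for the difference against cryoablation.

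With the erythroid covariate the direction turned for Hba-a2 in A-C (0.18) and for anti-PD-1 after cryoablation (0.038), for Hba-a1 in A-C (0.50), for the erythroid list for anti-PD-1 after cryoablation (0.038) and for its mean effect (0.021), and for MHC class II presentation for anti-PD-1 after cryoablation (-0.093); the level of a list as a covariate removes that list by construction. For the erythroid list in R-C camera's direction turned there while the median stayed negative (-0.051, from -1.53). In 8 other cases a list lost its call and its median turned sign while camera's direction did not, with medians from -0.051 to 0.05. For genes that passed limma in neither fit a turned direction was not counted. With the keratinocyte covariate the direction turned for the keratinocyte list in A-R and R-C with antibody (-0.086 and 0.17) and for anti-PD-1 after cryo-thermal therapy (-0.06). It turned for endothelium in R-C with antibody as well (0.08). It also turned for keratinocytes in A-R with antibody without skin-rich tumours (-0.19) and without cryo-thermal plus anti-PD-1 replicate 1 (-0.194, up to 1.649 without its replicate 3), and for endothelium in R-C with antibody without radiofrequency plus anti-PD-1 replicate 3 (0.077, down to -0.273 without its replicate 2).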

Other observations

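The cryoablation tumours without anti-PD-1 stood apart in heat shock chaperones, the RNA-binding protein gene Cirbp and liver transcripts in particular. The lists behind these values, the skin pattern with its test, the fits with the keratinocyte, erythroid, Jchain or B and plasma cell level as a covariate and those without cryo-thermal replicates 1 and 2 were chosen after the results were seen. Against the mean of the other 5 groups, 16 of 18 chaperone genes were lower, with a median log2 difference of -0.44 (median SE of the genes 0.07). This comparison was not among the 13 planned ones and was also chosen after the results were seen. No list test or regrouping was run for it, so its values describe the pattern and do not test it. Hsph1 had -1.04, Stip1 -0.53 and Hspa8 -0.42. Cirbp, which cold induces in many cells, was higher by 0.79 (adjusted p = 0.000383), and Rbm3, another such gene, had 0.40 (adjusted p = 0.0985). The mean log2 level of liver secreted proteins, 4 genes past the filter, was 2.12, 2.87 and 3.10 in these 3 tumours, 2.86 in cryoablation plus anti-PD-1 replicate 2 and between 1.00 and 1.94 in the other 14 tumours.

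Of the B and plasma cell list 1 gene passed the filter, Jchain, with log2 levels of 2.53 and 2.34 in cryo-thermal replicates 1 and 2, 1.36 in cryoablation plus anti-PD-1 replicate 1 and at most 0.89 in the other 15 tumours. The B cell genes Ms4a1 and Cd79a were highest in another tumour, radiofrequency replicate 3, at 0.325 and 1.91 FPKM, and measured 0.16 and 0.211 FPKM in cryo-thermal replicate 1 and 0.0436 and 0.181 FPKM in its replicate 2.

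Higher T cell and interferon gamma response genes after cryo-thermal therapy could come from the tissue make-up of the samples or from a single tumour. The interferon gamma list had a median of 1.63 (median SE of the genes 0.294) against the mean of the other ablations, with 17 of 17 genes higher. With the keratinocyte level as a covariate it kept 100% of this median, and with the erythroid level 91.5% (1.49, 17 of 17 higher). With any single cryo-thermal tumour left out it kept at least 94.1%. The T cell list had a median of 0.85, and of 0.85 and 0.78 with these covariates. It was at least 0.73 with any single tumour left out. For this averaged comparison, in which neither the keratinocyte nor the erythroid list passed, these values argue against skin, blood and a single tumour as the whole cause. Against cryoablation alone the erythroid median was -3.32 and the gene calls were lost with the erythroid covariate. Its level was 6.05 to 6.49 after cryoablation and 2.14 to 4.67 after cryo-thermal therapy, so it nearly follows the groups. The lost calls therefore decide nothing. Less blood after cryo-thermal therapy cannot add these transcripts. Less dilution by blood would raise all other genes alike, yet the median over 12587 genes was -0.009. The interferon gamma list had 2.52 and the T cell list 0.86. These values argue against blood as the source of both rises.

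Lymphoid tissue taken with the tumour, which could bring T cells and antibody-secreting cells together, stays open for the T cell genes. With the Jchain level as a covariate, run first, the T cell median kept 44.5% of its value against the mean of the other ablations. It went from 0.85 to 0.38, and the median SE of the genes from 0.15 to 0.17. Against cryoablation alone it kept 17.1%, from 0.86 to 0.15, and the median SE of the genes went from 0.24 to 0.29. In both cases 0 T cell genes passed limma, in the first through a lower median and a slightly wider error. With the mean of all 13 measured B and plasma cell genes, run second, it kept 82% and 62.7%, with 8 and 0 of 12 past limma. The first covariate alone met the rule set for lymphoid tissue as the cause in both comparisons. The second was added after that result. The 2 measures disagree, and most of the 13 genes lie near 0. Cells that enter a tumour in an immune response would also give the same values as tissue taken with it. Without cryo-thermal replicates 1 and 2, which leaves 1 tumour of that group that is assumed to vary like the other groups, the T cell median was 0.59 and 0.35, 69.5% and 41% of its value. In these 2 comparisons the limma count over all genes fell from 2243 and 1884 to 0 and 0, and it was 0 and 0 with Jchain and 715 and 0 with the 13 genes as a covariate. The interferon gamma median kept 93.6% and 90.6% without the 2 tumours, 73.8% and 68.5% with Jchain and 102.3% and 98.1% with the 13 genes. After cryo-thermal therapy plus anti-PD-1 the T cell level was 1.92 to 2.03 in the 3 tumours with Jchain at 0.60 to 0.89. Treatment itself is the biological difference the design names, and it stays open beside this, untested.

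The chaperone and Cirbp pattern after cryoablation alone may reflect time of day, handling or blood. The clock output genes had a median of -0.03 with 3 of 11 past limma in both directions, Per1 at 0.96, Ciart at -0.53 and Cry1 at -0.40, and the positive arm had a median of 0.01 with Nfil3 at -0.46, so time of day stays open. Of 9 immediate early genes 8 had a positive difference, and the median was 0.25 (median SE of the genes 0.192, SD 0.53 over the genes). Handling stress was predicted to lower these genes as a set, and a median on the other side was to count against it. The test run also required a median clear of the spread over the genes and no gene lower. Atf3 at -1.01 (adjusted p = 0.00274), the 1 past limma, was lower like the chaperones, so handling stress stays open too. With the erythroid level as a covariate the chaperone median was -0.45 (median SE of the genes 0.10), 102.4% of its value, which argues against blood as its source. Yet 0 of 18 genes passed limma because the errors widened, so the calls were not kept. No biological explanation was tested.

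Keratinocyte genes varied between tumours of one group. Skin taken with the tumour is a candidate source: deviations from group means of the keratinocyte list and of 2 hair follicle genes, Krt27 and Tchh, had Spearman rho = 0.79 (permutation p = 8e-04) and Pearson r = 0.778 (permutation p = 0.0015) over 18 tumours, with 10000 permutations within groups. Without the 2 tumours farthest from the median r was 0.779 over 16 tumours. The keratinocyte list itself holds the hair root sheath keratins Krt71 and Krt25, so this correlation is not independent evidence of skin. No biological explanation was tested.

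Other splits of the same tumours were counted for every comparison. Cryo-thermal therapy against the mean of the other ablations had 2243 genes and the mean anti-PD-1 effect 1262. For both, only 1 of 100 regroupings, the real one, gave as many genes, so a chance split of these tumours is unlikely. The highest other counts were 4 and 389. Regroupings treat the tumours as exchangeable, so a chance difference between animals was not tested if tumours of a group share an animal. For the 9 comparisons between 2 groups the 10 splits are too few for a share under 0.05. The real count and the highest other were 1884 and 0 for cryo-thermal therapy against cryoablation, 1 and 10 against radiofrequency, and 1 and 0 for radiofrequency against cryoablation. With anti-PD-1 in both they were 511 and 7, 165 and 0, and 0 and 1 for the same pairs. For anti-PD-1 after cryoablation, radiofrequency and cryo-thermal therapy they were 543 and 6, 6 and 23, and 47 and 0. As many genes came from 3 of 10 splits for cryo-thermal therapy against radiofrequency, 2 of 10 for anti-PD-1 after radiofrequency and 1 of 10 for the others, except radiofrequency against cryoablation with anti-PD-1, where a real count of 0 decides nothing.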
